A study of Mus musculus with 9 samples.

How the data were processed

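The study measured gene expression with 1-colour Affymetrix whole-transcript arrays in 9 mouse samples, each hybridised with biotin-labelled total RNA. Per the submitters' processing notes the authors normalised the arrays with RMA, and the deposited values are RMA expression values on a log2 scale. Software versions, the probe set definition and the genome build of the probe design were not given in the sources used here. The deposited values were checked for scale and were used as they stand: the array medians lay between 5.80 and 5.92 and the values were not centred by gene.

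The table held 30177 probe sets, of which 23410 carried a gene annotation. Those with exactly 1 gene symbol (21789) were used, those with several symbols (1621) and those without a symbol (6767) were left out of the comparisons, and 21698 were matched to the reference by gene identifier, with 0 symbols renamed. Where a gene had several probe sets (998 of 19938 genes), the one with the highest mean over the 9 arrays stood for the gene, and for 140 genes another probe set had an opposed difference. Genes were kept if at least 1 array lay above the median of all probe sets on that array, which left 12018. The gene Ly6c2 was not analysed here.

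Samples fell into 6 groups by the deposited sample descriptions. WT Mo-DCs in GM-CSF + IL-4, WT Mo-DCs in GM-CSF and IRF4KO Mo-DCs in GM-CSF + IL-4 had 2 arrays each, while Ly6Chi monocytes, Ly6Clo monocytes and CD24+ DCs had 1 each. For the Ly6Clo TremL4+ monocyte sample 1 label field reads Ly-6Chi, and the title and sort description were followed. The deposit set (5 arrays in the earlier set A, 4 in the later set B) was read from the labels, which fill 1 field in 2 ways, and it is not stated to be a technical batch. Set A holds replicate 1 of both WT cultures and the 3 single arrays, set B holds replicate 2 of both WT cultures and both IRF4KO arrays.

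Differences were tested in R 4.3.3 with limma 3.58.1 (lmFit and eBayes), with 1 mean per group over all 9 arrays, so that the 3 replicated groups gave the spread (3 residual degrees of freedom) that genes share through eBayes. Benjamini-Hochberg adjusted p-values were computed over the genes tested in each of 5 comparisons, and a gene was called at an adjusted p under 0.05 (two-sided). Errors of log2 differences are limma's standard errors. Where a group had 1 array, the test assumes that it varies like the replicated groups. Ly6Clo and Ly6Chi monocytes, 1 array against 1, were compared without a test of genes, and lists were placed among 10000 random lists of equal size matched on mean expression.

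The comparisons, the filter, the alternatives, the rule for named genes and 34 gene lists were written before the data were examined. The lists cover DC, monocyte and macrophage subsets, cytokine target genes, antigen presentation, metabolism, stress, transcription factors, sort markers and markers of other cell types. The 32 lists with at least 5 measured members, apart from the sort markers, were tested with limma's camera at its preset correlation of 0.01, adjusted over the lists of a comparison, and again with an estimated correlation. No call of a list held with an estimated correlation, in any of the 5 comparisons. That correlation was estimated from 3 residual degrees of freedom, and this version was not tried on a list with a simulated shift. A call lost in this way therefore does not decide whether a list changed. Counts of called members were also adjusted over the list alone.

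Genes are named by this rule. It takes Irf4 and the sort markers, the 10 largest rises and the 10 largest falls among called genes whose arrays do not overlap between groups, up to 4 members with the largest difference of each list described, any DC or monocyte transcription factor, and the 10 genes with the largest product of both changes among those called in both the IL-4 and the IRF4KO comparison. Names without a known function could be passed over.

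Alternatives were no filter on low signal, a stricter filter (mean over the 9 arrays above the median of all probe set means, 10185 genes), another quantile normalization, the mean of a gene's probe sets, eBayes with trend and robust settings, the 4 arrays of a comparison alone, replicate number as a block, deposit set as a block, and each replicate left out in turn. For genes shared by the IL-4 and IRF4KO comparisons, the expected count is that of independent lists, and the correlation that shared WT arrays give was simulated in 100 draws. The same correlation was computed with different WT arrays in each comparison.

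The pipeline was tested on simulated data with the spread of these arrays, 12018 genes and 200 changed genes. Changes of 4-fold were recovered in 97.0% of genes for IRF4KO against WT, 99.0% for IL-4 and 96.0% to 96.5% for the comparisons with a single array. Changes of 2-fold were recovered in 42.0%, 63.0% and 0.0%. The changed genes were drawn at random, so that these percentages do not hold for genes with a larger spread. With IL-4, for example, Chil3 differed 15.5-fold (SE 0.85 on the log2 scale) and was not called. An uncalled gene can therefore differ by 4-fold or more. A list shifted by 1 log2 unit was found and 0 lists were called without a shift. The simulated genes varied independently of each other, so that this does not test whether the preset correlation holds for these arrays. Tables and figures were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.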

Results

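Gene expression was measured on 9 whole-transcript arrays from mouse mononuclear phagocytes, 1 array per sample in 6 groups. Of these groups, 3 were monocyte-derived dendritic cells (Mo-DCs) grown for 72 h from bone marrow Ly6Chi TremL4− monocytes and sorted as Ly-6Clo CD11c+ cells. Wild-type (WT) cells grew in GM-CSF (2 arrays) or in GM-CSF + IL-4 (2 arrays), and cells without the transcription factor IRF4 (IRF4KO) grew in GM-CSF + IL-4 (2 arrays). The other groups had 1 array each, from WT bone marrow Ly6Chi TremL4− monocytes, from WT bone marrow Ly6Clo TremL4+ monocytes and from WT splenic CD24+ dendritic cells (DCs). Median log2 signals of the 9 arrays lay between 5.80 and 5.92. Across genes, Pearson's r between both arrays of a group was 0.960 for WT GM-CSF + IL-4, 0.960 for WT GM-CSF and 0.979 for IRF4KO, where genes are not independent replicates. Both IRF4KO arrays belong to the later deposit set, while each WT pair spans both sets. The r of IRF4KO is therefore not comparable with those of WT. The sources do not say whether the 2 arrays of a group came from separate cultures or animals, and the number of arrays limits the precision.

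The comparison of IRF4KO with WT Mo-DCs, both in GM-CSF + IL-4, asked which genes depend on IRF4 when monocytes become DCs. Irf4 itself stood at 4.60 ± 0.15 (log2 signal, SD, n = 2) in IRF4KO cells and at 9.91 ± 0.22 (SD, n = 2) in WT cells, a fall of 39.8-fold (limma adjusted p = 4.8e-04). The genes that fell most included Ccl22 (140-fold, log2 difference −7.13 ± 0.30 SE) and Ccl17 (122-fold, −6.93 ± 0.23), whose chemokines attract T cells through CCR4, and Aldh1a2 (90.3-fold), which makes retinoic acid from retinal. Plet1 fell 118-fold, the chemokine receptor gene Cxcr2 fell 110-fold, Kynu of the kynurenine pathway fell 62.5-fold, the claudin gene Cldn1 fell 56.5-fold, Ccl5 fell 54.8-fold and the orphan nuclear receptor gene Nr4a3 fell 54.3-fold. In the other direction, Bex1 rose 138-fold (7.11 ± 0.64), the collagenase gene Mmp13 rose 95.1-fold (6.57 ± 0.27) and the carbonic anhydrase gene Car6 rose 92.1-fold (6.53 ± 0.20). Rbp4, which carries retinol, rose 39.5-fold, the cholesterol hydroxylase gene Ch25h rose 39.0-fold and Cd93 rose 33.8-fold. For each of these genes both IRF4KO arrays lay on the same side of both WT arrays. The rule for naming the largest changes requires this, so that it is no separate check. In all, limma called 1304 genes higher and 1237 lower in IRF4KO cells among 12018 tested, 835 and 754 of them by 2-fold or more. With the deposit set as a block the counts were 1723 higher and 1566 lower. Fewer genes were called without WT GM-CSF + IL-4 replicate 1, which leaves the later set alone for this comparison. All 2541 calls kept their direction within that set. Its arrays also helped to make the calls, so that the kept direction is no separate check. Without IRF4KO replicate 1 the calls numbered 480, without IRF4KO replicate 2 they numbered 662, and without WT GM-CSF + IL-4 replicate 2 they numbered 1440. Of 84 genes named for this comparison, 43 lost their call without IRF4KO replicate 1 (Aldh1a2 at an adjusted p of 0.0658, Nr4a3 at 0.0741), 36 without IRF4KO replicate 2, 5 and 15 without WT GM-CSF + IL-4 replicates 1 and 2, and 1 without either WT GM-CSF replicate.

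Of 24 costimulation and maturation genes, 21 fell and 0 rose in IRF4KO cells, also when adjusted over the list alone, among them Fscn1 (31.5-fold), whose product bundles actin in mature DCs, and Ccr7 (26.2-fold), the receptor that guides DCs to lymph nodes. The list's median log2 difference was −2.28 (camera adjusted p = 1.8e-11, and adjusted p = 0.736 with an estimated correlation), −1.97 within the later deposit set and −2.25 with deposit set as a block. Of 21 genes shared by conventional DCs, 16 fell and 1 rose (16 and 2 adjusted over the list alone), with Kmo 45.4-fold, P2ry10 36.6-fold and the TNF receptor adaptor gene Traf1 21.0-fold lower. Their median was −1.78 (camera adjusted p = 2.2e-07, and adjusted p = 0.736 with an estimated correlation), −1.88 within the later set and −2.03 with the block. Of 16 genes of MHC class II presentation, 9 fell and 1 rose (9 and 2 adjusted over the list alone), including H2-Eb1 (19.3-fold), H2-Aa (9.59-fold), H2-Oa (8.97-fold), the invariant chain gene Cd74 (8.16-fold) and H2-Ab1 (7.16-fold). The class II list had a camera adjusted p = 0.00384, and adjusted p = 0.736 with an estimated correlation. Among 29 genes of MHC class I and cross-presentation, 10 fell and 2 rose (10 and 4 adjusted over the list alone), and the list as a whole was not called (camera adjusted p = 0.19). Its members with the largest differences were Cybb, an NADPH oxidase subunit, which rose 8.81-fold, and Rab27a, Wdfy4 and Psme2, which fell by 2.31, 2.01 and 1.71 on the log2 scale. Of 33 cell cycle genes, 6 fell and 0 rose, also when adjusted over the list alone, including the helicase subunit gene Mcm6 (3.09-fold). The cell cycle list had a camera adjusted p = 0.00133 and adjusted p = 0.859 with an estimated correlation. It was 0.0574 without WT GM-CSF + IL-4 replicate 1 and 0.181 without IRF4KO replicate 1. Without IRF4KO replicate 1 the limma adjusted p was 0.0641 for Fscn1 and 0.11 for Ccr7, and without IRF4KO replicate 2 it was 0.0704 and 0.103. H2 genes resemble each other closely, and shared probe signal between them was not examined.

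Of 29 lysosome genes, 20 rose and 0 fell in IRF4KO cells (23 and 0 adjusted over the list alone), with a median log2 difference of 1.45 (camera adjusted p = 1.8e-11, and adjusted p = 0.736 with an estimated correlation), 1.59 within the later deposit set and 1.60 with deposit set as a block. Gpnmb rose 14-fold (3.81 ± 0.58 SE), the proton pump subunit gene Atp6v0d2 rose 12.1-fold, the alpha-galactosidase gene Gla rose 10.3-fold and the cathepsin gene Ctsl rose 7.80-fold. Of 24 macrophage genes, 15 rose and 1 fell (18 and 3 adjusted over the list alone), with a median of 1.5 (camera adjusted p = 4.2e-06, and adjusted p = 0.736 with an estimated correlation), 1.56 within the later set and 1.69 with the block. The mannose receptor gene Mrc1 rose 19.8-fold (4.31 ± 0.71), the RNA sensor gene Tlr7 rose 15.8-fold and Cd68 rose 5.56-fold. Outside the naming rule, Axl fell 2.92-fold, and C1qa and C1qb fell when adjusted over the list alone (log2 differences −0.57 and −0.63). C1qc and Adgre1 had log2 differences of −0.02 and 0.76 (limma adjusted p = 0.939 and 0.433). Gpnmb and Ctsd belong to both the lysosome and the macrophage list. Of 22 genes of lipid uptake and PPARγ or LXR targets, 8 rose and 1 fell (9 and 1 adjusted over the list alone), with Pparg 8.13-fold, the fatty acid carrier gene Fabp4 6.41-fold, the lysosomal lipase gene Lipa 4.99-fold and the lipid droplet gene Plin2 4.64-fold higher. This list had a camera adjusted p = 0.00389 and adjusted p = 0.758 with an estimated correlation. Of 22 genes of the unfolded protein response and amino acid stress, 12 rose and 1 fell (13 and 1 adjusted over the list alone), including Asns (7.90-fold), which makes asparagine, and the stress regulators Ddit3 (4.14-fold) and Trib3 (3.92-fold). The stress list had a camera adjusted p = 3.8e-04 and adjusted p = 0.736 with an estimated correlation. Without IRF4KO replicate 1 the limma adjusted p was 0.0932 for Gpnmb, 0.0969 for Mrc1 and 0.0872 for Pparg, and without IRF4KO replicate 2 it was 0.0837, 0.1 and 0.0938.

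Among classical monocyte genes, 7 of 21 were higher and 1 lower in IRF4KO cells (9 and 1 adjusted over the list alone), including the collagenase gene Mmp8 (20.3-fold) and the fibronectin gene Fn1 (10.7-fold). That list had a camera adjusted p = 0.0458 and adjusted p = 0.859 with an estimated correlation. It was 0.248 without WT GM-CSF + IL-4 replicate 2, 0.139 without IRF4KO replicate 2, 0.052 with the stricter filter and 0.0587 after another quantile normalization. Of 16 Fc and complement receptor genes, 7 rose and 1 fell (7 and 2 adjusted over the list alone), including C3ar1 (4.10-fold) and Itgam (3.61-fold). The receptor list had a camera adjusted p = 0.0335 and adjusted p = 0.758 with an estimated correlation. It was 0.0835 without WT GM-CSF + IL-4 replicate 2, 0.0822 without IRF4KO replicate 2, 0.0588 with no filter and 0.0802 with the stricter filter. IL-4 and STAT6 target genes went both ways, with 12 of 35 higher and 10 lower, the same counts adjusted over the list alone (camera adjusted p = 0.999), and the list's median of −0.15 and mean of 0.04 differed in sign.

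Among 39 transcription factor genes of DCs and monocytes, 8 rose and 16 fell in IRF4KO cells (12 and 17 adjusted over the list alone; camera adjusted p = 0.154). Irf4 itself, which the genotype removes, is 1 of the 16 that fell. Irf5, which drives inflammatory cytokine genes, fell 7.99-fold, the repressor gene Bcl6 fell 5.82-fold and Batf3, which cDC1 development needs, fell 4.01-fold. Stat5a fell 3.85-fold, the NF-κB subunit gene Relb fell 3.43-fold and Zbtb46, a marker of conventional DCs, fell 2.75-fold. Zeb2 rose 4.56-fold and Klf4, a regulator of monocyte differentiation, rose 3.63-fold, with limma adjusted p of 0.0622 and 0.123 without IRF4KO replicate 1. Irf8 had a log2 difference of 0.23 ± 0.19 (SE, 2 arrays against 2; limma adjusted p = 0.46). Of 20 genes of CD24+ or CD8+ DCs (cDC1), 6 fell and 3 rose (7 and 3 adjusted over the list alone; camera adjusted p = 0.281). Clec9a, a cDC1 receptor for dead cells, was among those that rose, by 10.4-fold (3.38 ± 0.65 SE, limma adjusted p = 0.0176). Without IRF4KO replicate 1 its adjusted p was 0.0841, without WT GM-CSF + IL-4 replicate 1 it was 0.088, and without WT GM-CSF + IL-4 replicate 2 it was 0.094. Of the genes for the sort markers, Sirpa rose 3.65-fold, while the log2 differences were 0.04 ± 0.16 for Itgax, 0.02 ± 0.43 for Csf1r and −0.61 ± 0.17 for Cd24a (limma adjusted p = 0.899, 0.984 and 0.0565). The signs of Itgax and Csf1r turned without WT GM-CSF + IL-4 replicate 2 or IRF4KO replicate 2, to −0.06 and −0.08 for Itgax and to −0.49 and −0.28 for Csf1r. Markers of other cells included 1 risen and 0 fallen of 7 B cell genes, 1 and 0 of 8 T and NK cell genes, 2 and 0 of 7 mast cell and basophil genes, 0 and 1 of 5 erythroid genes, 2 and 2 of 12 neutrophil genes (median −0.95, and 0.03 within the later deposit set), 1 and 2 of 12 early myeloid progenitor genes and 1 and 4 of 7 plasmacytoid DC genes. The plasmacytoid DC gene that rose was Cox6a2, a cytochrome oxidase subunit, by 14.7-fold. None of these 7 marker lists was called by camera, the lowest adjusted p being 0.423, for plasmacytoid DCs (median −0.77, mean 0.01).

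**Figure D1:**
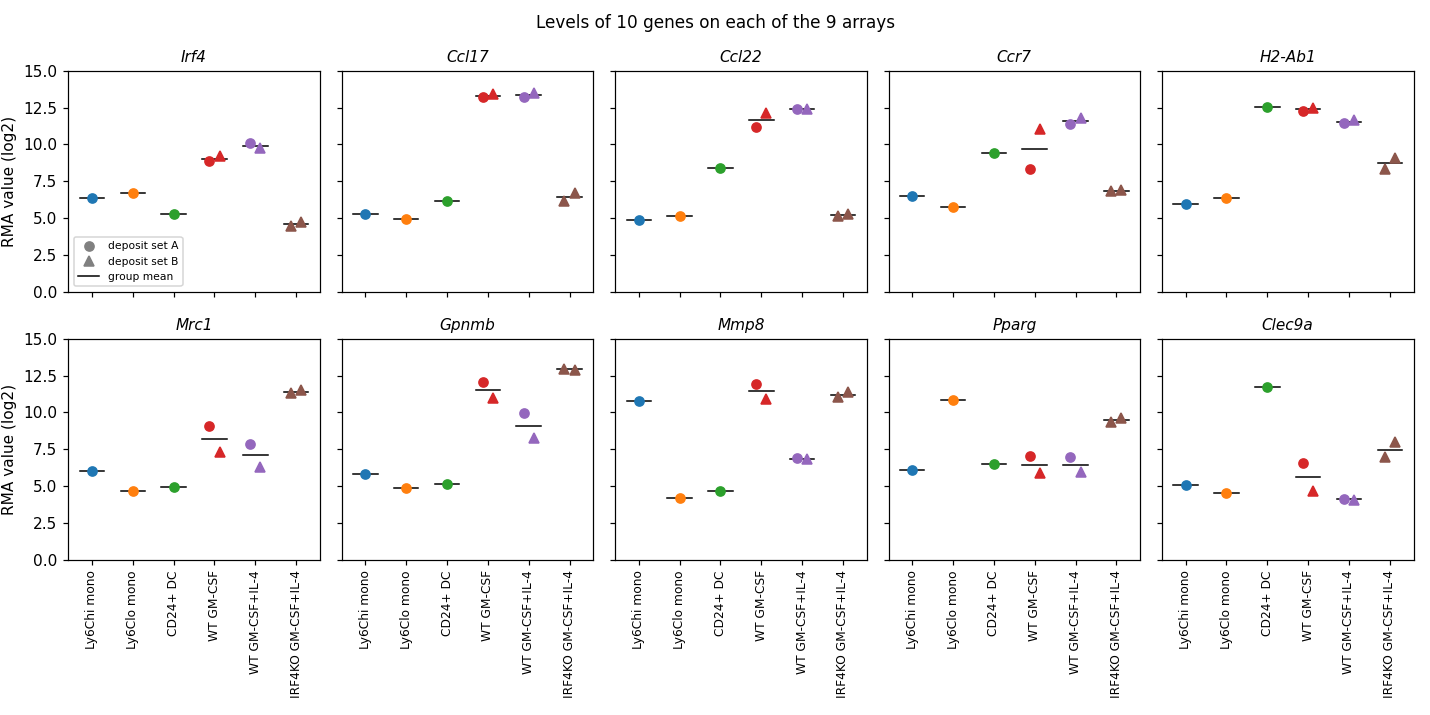
Log2 signal of Irf4 and other genes named in the text on each of the 9 arrays, by group. Circles are arrays of the earlier deposit set, triangles arrays of the later set, and the black line is the group mean. The 2 IRF4KO arrays had Irf4 signals of 4.49 and 4.71, below the other arrays.

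**Figure D2:**
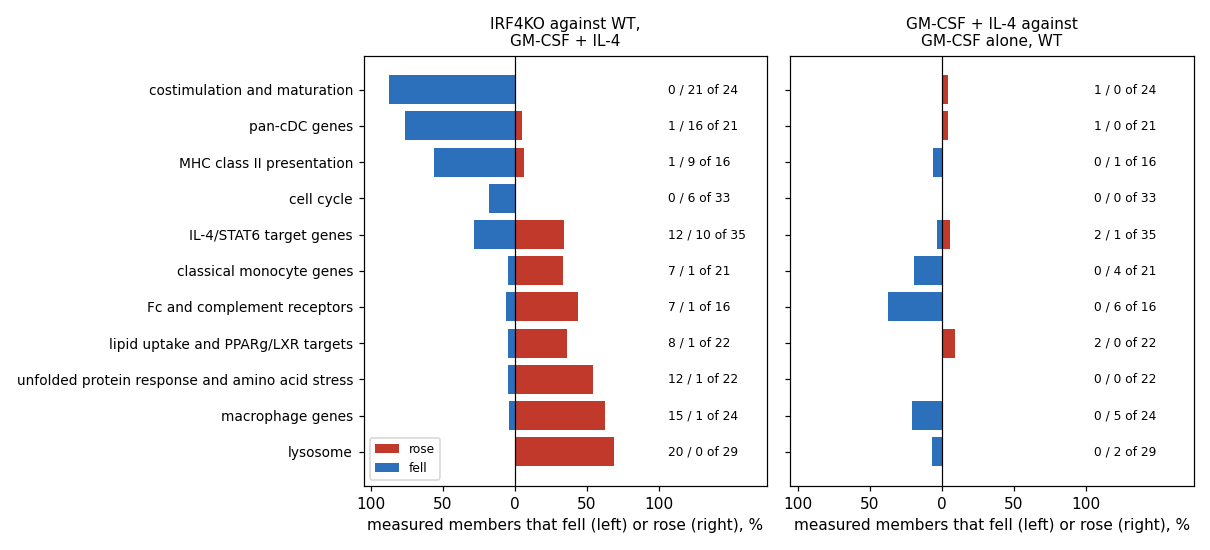
Percent of the measured members of each gene list that limma called higher (right) or lower (left), for IRF4KO against WT Mo-DCs and for GM-CSF + IL-4 against GM-CSF alone, with the counts that rose and fell beside each bar. In IRF4KO cells 21 of 24 costimulation and maturation genes were lower and 20 of 29 lysosome genes were higher.

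The effect of IL-4 was measured in WT Mo-DCs as GM-CSF + IL-4 against GM-CSF alone, with 2 arrays each. Ccl24, whose product attracts eosinophils, rose 47.0-fold with IL-4 (log2 difference 5.55 ± 0.21 SE, limma adjusted p = 0.00258), the T cell and phagocyte receptor gene Slamf1 rose 20.7-fold (4.37 ± 0.71) and Cxcr2 rose 11.6-fold (3.54 ± 0.29). Ramp3 rose 8.66-fold, the semaphorin gene Sema7a 6.48-fold, the proenkephalin gene Penk 6.34-fold and the adhesion receptor gene Cd226 5.21-fold. The protease inhibitor gene Serpinb2 fell 27.6-fold (−4.79 ± 0.47), Mmp8 fell 23.6-fold (−4.56 ± 0.33), Ifitm6 fell 14.7-fold, the matrix gene Thbs1 fell 13.2-fold, Stap1 fell 10.5-fold and Adgre4 fell 9.76-fold. In each of these genes the arrays of both cultures did not overlap, which the rule for naming the largest changes requires. Irf4 stood at 9.04 ± 0.22 (log2 signal, SD, n = 2) in GM-CSF, with a log2 difference of 0.88 ± 0.19 with IL-4 (limma adjusted p = 0.0904). limma called 86 genes higher and 181 lower with IL-4, 72 and 169 of them by 2-fold or more.

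Of 16 Fc and complement receptor genes, 6 fell and 0 rose with IL-4 (13 and 0 adjusted over the list alone), including the high-affinity IgG receptor gene Fcgr1 (9.61-fold) and C5ar1 (8.28-fold). Their camera adjusted p was 1.9e-15, and adjusted p = 0.256 with an estimated correlation. Of 24 macrophage genes, 5 fell and 0 rose (17 and 1 adjusted over the list alone), including the complement genes C1qb (9.49-fold) and C1qc (7.93-fold). The macrophage list had a camera adjusted p = 1.1e-13 and adjusted p = 0.256 with an estimated correlation. Of 21 classical monocyte genes, 4 fell and 0 rose (10 and 1 adjusted over the list alone). For classical monocyte genes camera gave adjusted p = 2.4e-06, and adjusted p = 0.518 with an estimated correlation. Of 18 cDC2 genes, 4 fell and 0 rose (11 and 2 adjusted over the list alone), including the lectin gene Cd209c (7.94-fold). For cDC2 genes camera gave adjusted p = 2.3e-06, and adjusted p = 0.256 with an estimated correlation. Of 27 C-type lectin and scavenger receptor genes, 2 fell, the scavenger receptor gene Msr1 (8.39-fold) and Cd209c, and 1 rose (10 and 1 adjusted over the list alone). For C-type lectin and scavenger receptor genes camera gave adjusted p = 2.8e-05, and adjusted p = 0.518 with an estimated correlation. Of 29 lysosome genes, 2 fell and 0 rose (12 and 0 adjusted over the list alone). For lysosome genes camera gave adjusted p = 3.6e-09, and adjusted p = 0.518 with an estimated correlation. Of 7 mast cell and basophil genes, 3 fell and 0 rose (4 and 0 adjusted over the list alone), including Cd200r3 (9.10-fold). For mast cell and basophil genes camera gave adjusted p = 6.9e-04, and adjusted p = 0.256 with an estimated correlation. Of 12 neutrophil genes, 3 fell, Mmp8 among them, and 1 rose, Cxcr2 (4 and 1 adjusted over the list alone). For neutrophil genes camera gave adjusted p = 0.0145, and adjusted p = 0.586 with an estimated correlation, and the camera value was 0.07 with the stricter filter, 0.493 without WT GM-CSF + IL-4 replicate 2 and 0.0854 without WT GM-CSF replicate 1. Among 16 MHC class II genes, 1 fell and 0 rose (4 and 0 adjusted over the list alone). For MHC class II genes camera gave adjusted p = 0.00149, and adjusted p = 0.256 with an estimated correlation. Among 26 interferon-stimulated genes, 1 fell, Rtp4 (3.24-fold), and 0 rose (5 and 0 adjusted over the list alone). For interferon-stimulated genes camera gave adjusted p = 1.6e-04, and adjusted p = 0.402 with an estimated correlation. Of 33 cell cycle genes limma called 0, also when adjusted over the list alone, with a list median of −0.42, or −0.13 within the earlier and −0.92 within the later deposit set (camera adjusted p = 4.0e-04, and adjusted p = 0.662 with an estimated correlation), and the camera value was 0.13 without WT GM-CSF + IL-4 replicate 2 and 0.129 without WT GM-CSF replicate 2.

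Of 24 costimulation and maturation genes, 1 rose and 0 fell with IL-4 over all genes tested, against 14 and 1 adjusted over the list alone, with a median of 0.98, or 1.51 within the earlier and 0.61 within the later deposit set (camera adjusted p = 4.2e-09, and adjusted p = 0.518 with an estimated correlation). The log2 differences were 2.71 ± 0.46 for Cd200, 2.67 for Fscn1, 2.59 for Cd83 and 1.94 for Cd86 (limma adjusted p = 0.051, 0.118, 0.132 and 0.121). With deposit set as a block Cd200, Fscn1 and Cd86 were called (adjusted p = 0.0114, 0.0399 and 0.0416), and Cd83 was not (0.0644). Cd200 was also called with the stricter filter (0.0471) and with another quantile normalization, and Cd200, Fscn1 and Cd83 without WT GM-CSF replicate 2. Of 21 genes shared by conventional DCs, 1 rose and 0 fell (9 and 3 adjusted over the list alone; camera adjusted p = 0.00557, and adjusted p = 0.586 with an estimated correlation), and the camera value was 0.0644 without WT GM-CSF + IL-4 replicate 2 and 0.221 without WT GM-CSF replicate 1. Of 35 IL-4 and STAT6 target genes, 2 rose and 1 fell (8 and 6 adjusted over the list alone; camera adjusted p = 0.414), Ccl24 among those that rose, while Chil3 and Rnase2a had log2 differences of 3.95 and 3.29 (limma adjusted p = 0.0897 and 0.216, and 0.00225 and 0.0127 with deposit set as a block). Among 39 transcription factor genes, Batf3 rose 3.31-fold and the aryl hydrocarbon receptor gene Ahr fell 3.98-fold (7 rose and 3 fell adjusted over the list alone; camera adjusted p = 0.818). Of the sort markers 0 were called by limma over all genes tested, and 0 rose and 6 fell of 7 adjusted over the list alone, with log2 differences of −2.40 for Csf1r and −1.05 for Sirpa, which were both called with deposit set as a block (adjusted p = 0.00642 and 0.0143). The IL-4 calls rested on the spread pooled over the 3 replicated groups, IRF4KO among them. Both IRF4KO arrays lie in the later deposit set, so that their spread leaves out any difference between sets. Its root mean square SD was 0.222, against 0.308 in WT GM-CSF + IL-4 and 0.297 in WT GM-CSF. limma called 0 genes in the 4 arrays of this comparison alone (1550 at an unadjusted p under 0.05), 0 without WT GM-CSF + IL-4 replicate 1 (1955), 0 without either IRF4KO replicate (1550), 26 without WT GM-CSF + IL-4 replicate 2, 13 without WT GM-CSF replicate 1 and 177 without WT GM-CSF replicate 2. Of 36 genes named for this comparison, 12 lost their call with no filter, among them Slamf1 and Ramp3 (adjusted p = 0.105 and 0.0637). With deposit set as a block 7 of the 36 gained a call and 0 lost one. limma then called 345 genes higher and 587 lower, and all 267 genes kept their direction within the earlier and within the later set. The same arrays made the 267 calls, so that the kept direction is no separate check.

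Genes that responded to IL-4 were then followed in IRF4KO cells, which had also received IL-4. Of the 86 genes higher with IL-4, 75 were lower in IRF4KO cells, against 8.9 for independent lists, and 1 was higher, Fabp4. Of the 181 genes lower with IL-4, 115 were higher in IRF4KO cells, against 19.6 for independent lists, and 11 were lower. Slamf1, Cxcr2, Ramp3, Penk, Sema7a, Ccl24 and Cd226 rose with IL-4 and fell in IRF4KO cells, while Mmp8, Cd93, Serpinb2, Ifitm6 and Cybb fell with IL-4 and rose in IRF4KO cells. Both comparisons use the WT GM-CSF + IL-4 arrays, which alone gives a simulated r of −0.50 across 12018 genes beside the measured −0.52. Sharing alone also gives opposite signs in 93.1% of the 267 genes with the lowest p for IL-4, where 85.8% was measured. The simulation takes arrays as independent, without any deviation shared within a deposit set, so that neither it nor independent lists settle the counts of 75 and 115. The covariance of the log2 differences was −0.236 against −0.027 simulated. With different WT arrays in each comparison, where sharing gives 0.00, r across genes was −0.53 with replicate 1 for IL-4 and −0.30 with replicate 2 for IL-4, and 86.5% and 69.3% of the 267 genes with the largest IL-4 difference in each split had opposite signs, against 49.9% simulated. In the first of these the IL-4 effect lies within the earlier deposit set and the IRF4KO effect within the later set. The counts of 75 and 115 were 0 and 0 without WT GM-CSF + IL-4 replicate 1 or either IRF4KO replicate, where limma called 0 genes for IL-4.

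**Figure D3:**
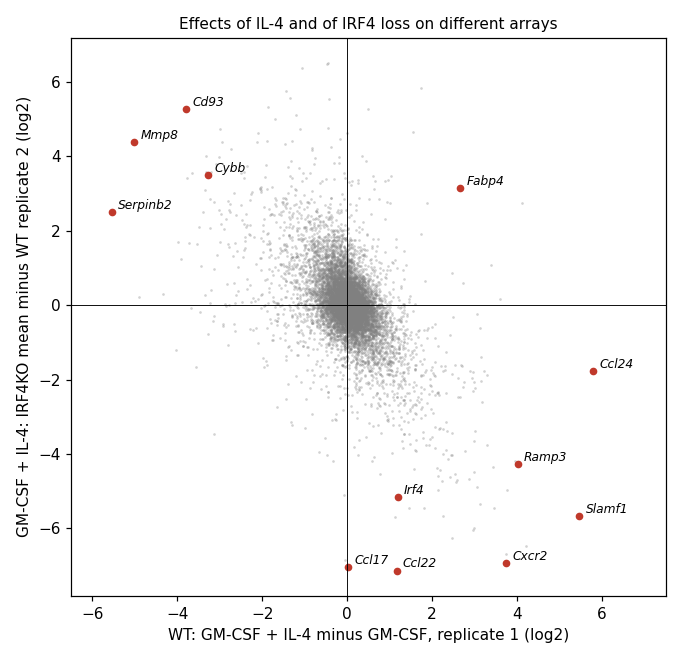
Log2 difference of the IRF4KO mean against WT GM-CSF + IL-4 replicate 2 (vertical axis) over the log2 difference of GM-CSF + IL-4 against GM-CSF alone in replicate 1 (horizontal axis), so that the axes share no array. Each of the 12018 grey points is 1 gene tested, and named red points include genes such as Slamf1 and Cxcr2 that were higher with IL-4 and lower in IRF4KO cells, with r across genes of −0.53.

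WT Mo-DCs in GM-CSF + IL-4 were compared with the Ly6Chi monocytes they came from, 2 arrays against 1. Ccl17 was 270-fold higher in the Mo-DCs (log2 difference 8.08 ± 0.28 SE), Ccl22 180-fold (7.49 ± 0.37), the elastase gene Mmp12 162-fold and Plet1 142-fold. Socs2, a feedback inhibitor of cytokine signals, was 113-fold higher, Aldh1a2 113-fold, the CD11c gene Itgax 70.3-fold (6.14 ± 0.19) and the PD-1 ligand gene Pdcd1lg2 63.9-fold. The Mo-DCs were sorted as CD11c+ cells, so that the sort itself selected for Itgax. Plac8 fell 140-fold (−7.13 ± 0.46), Ifitm6 132-fold, Ms4a6b 126-fold and the coagulation factor gene F13a1 108-fold (−6.76). The granule protease genes Ctsg and Elane fell 58.8-fold and 21.9-fold, as did the granule genes Mpo (33.6-fold) and Prtn3 (20-fold). limma called 852 genes higher and 1379 lower in Mo-DCs, 668 and 1081 of them by 2-fold or more.

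By group, 17 of 24 costimulation and maturation genes rose from monocyte to GM-CSF + IL-4 Mo-DC and 1 fell (18 and 1 adjusted over the list alone; camera adjusted p = 3.2e-12, and adjusted p = 0.629 with an estimated correlation). Of 16 MHC class II genes, 5 rose and 1 fell (6 and 1 adjusted over the list alone), with H2-Aa 55.4-fold, H2-Ab1 47.2-fold, H2-Eb1 42.1-fold and Cd74 29.8-fold higher (camera adjusted p = 0.00215, and adjusted p = 0.362 with an estimated correlation). Of 35 IL-4 and STAT6 target genes, 17 rose and 5 fell (18 and 5 adjusted over the list alone). For IL-4 and STAT6 target genes camera gave adjusted p = 5.0e-07, and adjusted p = 0.629 with an estimated correlation. Their median was 1.58 here and 1.40 in GM-CSF Mo-DCs against the same monocytes, so that most of this rise was also present without IL-4. Of 17 GM-CSF and STAT5 target genes, 9 rose and 0 fell (11 and 1 adjusted over the list alone), including the cyclin gene Ccnd2 (39.8-fold) and the signalling inhibitor gene Cish (26.6-fold). For GM-CSF and STAT5 target genes camera gave adjusted p = 1.2e-05, and adjusted p = 0.362 with an estimated correlation. Of 21 genes shared by conventional DCs, 15 rose and 2 fell (15 and 4 adjusted over the list alone). For genes shared by conventional DCs camera gave adjusted p = 5.8e-06, and adjusted p = 0.629 with an estimated correlation. Of 21 classical monocyte genes, 13 fell and 0 rose (14 and 1 adjusted over the list alone). For classical monocyte genes camera gave adjusted p = 4.1e-08, and adjusted p = 0.629 with an estimated correlation. Of 26 interferon-stimulated genes, 18 fell and 0 rose (21 and 0 adjusted over the list alone), including Ifit3 (20.9-fold), Ifi203 (18.4-fold) and Rtp4 (14.6-fold). For interferon-stimulated genes camera gave adjusted p = 3.2e-12, and adjusted p = 0.362 with an estimated correlation. Of 33 cell cycle genes, 23 fell and 0 rose (30 and 0 adjusted over the list alone), including Racgap1 (8.88-fold), the spindle motor gene Kif11 (7.60-fold) and Mki67 (6.49-fold). For cell cycle genes camera gave adjusted p = 6.5e-11, and adjusted p = 0.645 with an estimated correlation. Of 12 early myeloid progenitor genes, 5 fell and 1 rose, also when adjusted over the list alone (camera adjusted p = 0.0393, and adjusted p = 0.645 with an estimated correlation), and the camera value was 0.471 with the stricter filter, 0.133 without WT GM-CSF + IL-4 replicate 1, 0.0556 without either WT GM-CSF replicate and 0.086 without either IRF4KO replicate. Macrophage genes went both ways, 6 up and 6 down of 24 (6 and 8 adjusted over the list alone; camera adjusted p = 0.95), with Gpnmb 9.67-fold higher and Tlr7 12.3-fold, the lipoprotein gene Apoe 11.5-fold and the selenoprotein gene Selenop 10-fold lower. Of 20 cDC1 genes, 5 rose and 2 fell, the same counts adjusted over the list alone (camera adjusted p = 0.166).

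Of 39 transcription factor genes, 13 rose and 10 fell in GM-CSF + IL-4 Mo-DCs against the monocytes (15 and 14 adjusted over the list alone; camera adjusted p = 0.403). Nr4a3 rose 64.1-fold, Bhlhe40 29.6-fold, Egr2 25.8-fold, Irf4 11.6-fold (3.54 ± 0.23 SE, limma adjusted p = 9.2e-04), Batf3 10.7-fold, Relb 3.67-fold and Zbtb46 3.61-fold. Irf7, a regulator of the interferon response, fell 13.7-fold, Klf4 5.09-fold and Irf8 3.14-fold, and among sort marker genes Csf1r fell 5.81-fold and Sirpa 2.58-fold. These tests assume that the lone monocyte array varies as the replicated groups do. With deposit set as a block limma called 1189 genes higher and 1577 lower, and it called 1306 in all without WT GM-CSF + IL-4 replicate 2, which leaves the earlier set alone, 1454 without WT GM-CSF + IL-4 replicate 1 and 1287 without either IRF4KO replicate. Of 44 genes named for this comparison, 7 and 8 lost their call without WT GM-CSF + IL-4 replicates 1 and 2 (Nr4a3 at an adjusted p of 0.0522 and 0.0637, Klf4 at 0.072 and 0.103), 6 without either IRF4KO replicate and 2 without either WT GM-CSF replicate. Within the earlier set all 2231 calls kept their direction, but arrays of that set also made the calls, so that this is no separate check.

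Mo-DCs grown in GM-CSF alone were also compared with Ly6Chi monocytes, 2 arrays against 1. Mmp12 was 266-fold higher (log2 difference 8.05 ± 0.24 SE), Ccl17 262-fold (8.03 ± 0.28), the lectin gene Clec4n 137-fold (7.10 ± 0.47), Itgax 121-fold, Ccl22 111-fold, the platelet factor gene Pf4 104-fold and the aminopeptidase gene Anpep 89.9-fold. Here too the sort for CD11c+ cells selected for Itgax. Plac8 fell 75.9-fold (−6.25), F13a1 64.8-fold, Ctsg 51.4-fold, Mpo 30.6-fold, the chitinase-like gene Chil3 29.0-fold and the prostaglandin dehydrogenase gene Hpgd 22.5-fold. Irf4 rose 6.32-fold (2.66 ± 0.23, limma adjusted p = 0.00299). Batf3 rose 3.23-fold, Egr2 38.0-fold, Bhlhe40 28.5-fold and Zbtb46 2.35-fold, and Irf7 fell 8.95-fold. Of 17 GM-CSF and STAT5 target genes, 8 rose and 0 fell (10 and 0 adjusted over the list alone). For GM-CSF and STAT5 target genes camera gave adjusted p = 9.0e-10, and adjusted p = 0.192 with an estimated correlation. Of 16 MHC class II genes, 5 rose and 0 fell (6 and 0 adjusted over the list alone), with H2-Aa 86.0-fold and H2-Ab1 84.9-fold higher (camera adjusted p = 2.1e-06, and adjusted p = 0.192 with an estimated correlation). Of 24 costimulation and maturation genes, 9 rose and 0 fell (14 and 0 adjusted over the list alone; camera adjusted p = 2.4e-09, and adjusted p = 0.403 with an estimated correlation), and of 21 genes shared by conventional DCs, 9 rose and 2 fell (12 and 4 adjusted over the list alone; camera adjusted p = 8.8e-05, and adjusted p = 0.403 with an estimated correlation). Of 24 macrophage genes, 8 rose and 2 fell (10 and 2 adjusted over the list alone), with Gpnmb 50.9-fold, C1qb 27.5-fold and C1qc 14.4-fold higher and Apoe 10-fold lower (camera adjusted p = 3.0e-04, and adjusted p = 0.403 with an estimated correlation). Of 16 Fc and complement receptor genes, 6 rose and 0 fell (7 and 0 adjusted over the list alone). For Fc and complement receptor genes camera gave adjusted p = 4.8e-07, and adjusted p = 0.376 with an estimated correlation. Of 25 inflammatory cytokine and chemokine genes, 6 rose and 2 fell (14 and 3 adjusted over the list alone), including the neutrophil attractant gene Cxcl2 (57.9-fold). For inflammatory cytokine and chemokine genes camera gave adjusted p = 5.5e-05, and adjusted p = 0.403 with an estimated correlation.

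Of 26 interferon-stimulated genes, 15 fell and 0 rose in GM-CSF Mo-DCs against the monocytes (21 and 0 adjusted over the list alone), including Ifit3 (17.6-fold). For interferon-stimulated genes camera gave adjusted p = 1.3e-11, and adjusted p = 0.192 with an estimated correlation. Of 33 cell cycle genes, 12 fell and 0 rose (23 and 0 adjusted over the list alone; camera adjusted p = 9.0e-10, and adjusted p = 0.403 with an estimated correlation), and of 21 classical monocyte genes, 8 fell and 0 rose (11 and 2 adjusted over the list alone; camera adjusted p = 4.3e-04, and adjusted p = 0.403 with an estimated correlation). Csf1r had a log2 difference of −0.14 ± 0.53 (limma adjusted p = 0.918), which turned to 0.32 with deposit set as a block and to 0.27 without WT GM-CSF replicate 2. A direction kept within the earlier deposit set, as given below, is no separate check, since arrays of that set also made the calls. limma called 488 genes higher and 760 lower, 433 and 622 of them by 2-fold or more, again with a lone monocyte array. With deposit set as a block it called 893 higher and 1031 lower, and it called 603 in all without WT GM-CSF replicate 2 (the earlier set alone, where all 1248 calls kept their direction), 662 without WT GM-CSF replicate 1 and 518 without either IRF4KO replicate. Of 31 genes named for this comparison, 5 and 4 lost their call without WT GM-CSF replicates 1 and 2 (Batf3 at an adjusted p of 0.0873 and 0.109), 4 without either IRF4KO replicate and 1 without either WT GM-CSF + IL-4 replicate.

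WT Mo-DCs in GM-CSF + IL-4 were set against splenic CD24+ DCs, 2 arrays against 1, which differ in organ and in being freshly sorted. Genes lower in Mo-DCs were led by Clec9a (202-fold, log2 difference −7.66 ± 0.79 SE), the DNase gene Dnase1l3 (161-fold), Ifi205 (148-fold), Cxcl9 (130-fold), Plac8 (117-fold), the chemokine receptor gene Xcr1 (100-fold), Cd8a (51.4-fold), Nr4a1 (46.3-fold) and the RNA sensor gene Tlr3 (46.1-fold). Higher in Mo-DCs were Rnase2a (150-fold, 7.23), Ccl17 (149-fold), the lipoprotein lipase gene Lpl (132-fold), Cxcr2 (126-fold), Chil3 (115-fold), the lectin genes Mgl2 (113-fold) and Clec4n (68.7-fold), and Mmp12 (74.1-fold). limma called 827 genes higher and 767 lower in Mo-DCs, 671 and 611 of them by 2-fold or more. Of 20 cDC1 genes, 16 fell and 1 rose (17 and 1 adjusted over the list alone), the gene that rose being Plet1 (60.8-fold). The cDC1 median was −2.76 (camera adjusted p = 1.6e-13, and adjusted p = 0.177 with an estimated correlation). Of 35 IL-4 and STAT6 target genes, 15 rose and 1 fell (22 and 2 adjusted over the list alone). For IL-4 and STAT6 target genes camera gave adjusted p = 8.4e-09, and adjusted p = 0.406 with an estimated correlation. Of 24 costimulation and maturation genes, 9 rose and 2 fell (11 and 3 adjusted over the list alone), including Pdcd1lg2 (45.1-fold). For costimulation and maturation genes camera gave adjusted p = 4.6e-04, and adjusted p = 0.58 with an estimated correlation. Of 24 macrophage genes, 9 rose and 0 fell (10 and 2 adjusted over the list alone), including the cathepsin gene Ctsd (19.8-fold), Gpnmb (16-fold), the F4/80 gene Adgre1 (8.83-fold) and the efferocytosis receptor gene Axl (6.12-fold). For macrophage genes camera gave adjusted p = 8.8e-04, and adjusted p = 0.487 with an estimated correlation. Of 18 cDC2 genes, 7 rose and 2 fell (10 and 3 adjusted over the list alone; camera adjusted p = 0.00141, and adjusted p = 0.367 with an estimated correlation), Sirpa among those that rose (14.7-fold). Of 29 lysosome genes, 11 rose and 2 fell (12 and 3 adjusted over the list alone; camera adjusted p = 0.0631).

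Of 16 MHC class II genes, 6 were lower and 1 higher in Mo-DCs than in CD24+ DCs (10 and 1 adjusted over the list alone), including H2-Ob (14-fold), the class II transactivator gene Ciita (6.11-fold) and H2-Oa (6.06-fold). For MHC class II genes camera gave adjusted p = 8.8e-04, and adjusted p = 0.327 with an estimated correlation. Of 29 genes of MHC class I and cross-presentation, 3 fell and 0 rose, also when adjusted over the list alone, including Rab43 (5.55-fold) and Wdfy4 (3.80-fold; camera adjusted p = 0.0503). That camera value was 0.0303 without WT GM-CSF + IL-4 replicate 1, 0.0434 without either WT GM-CSF replicate, 0.0174 with no filter, 0.0475 with the stricter filter and 0.0293 with the mean of a gene's probes. Of 21 genes shared by conventional DCs, 6 fell and 1 rose, also when adjusted over the list alone, including the cytokine receptor gene Flt3 (35.4-fold). For genes shared by conventional DCs camera gave adjusted p = 0.00254, and adjusted p = 0.58 with an estimated correlation. Of 39 transcription factor genes, 6 rose and 10 fell (8 and 10 adjusted over the list alone; camera adjusted p = 0.43), and the list's median of 0.05 (0.3 within the earlier deposit set) and mean of −0.26 differed in sign. Irf4 was 25.4-fold higher (4.67 ± 0.23 SE, limma adjusted p = 3.0e-04) and Zeb2 8.03-fold higher, while Irf8, which cDC1 need, was 7.92-fold, Klf2 5.11-fold and Bcl6 4.95-fold lower. Batf3 and Zbtb46 had log2 differences of 0.19 ± 0.31 and −0.47 (limma adjusted p = 0.786 and 0.188). Immediate early and heat shock genes, which cell isolation can induce, were lower in the Mo-DCs in 15 of 21 cases with 0 higher (18 and 0 adjusted over the list alone), including the chaperone gene Hspa1a (43.2-fold), Fos (23.2-fold) and Btg2 (11-fold; camera adjusted p = 5.3e-13, and adjusted p = 0.327 with an estimated correlation). The same list had a median 1.94 log2 units higher on the CD24+ DC array than on the mean of both monocyte arrays. Of 7 B cell genes, 3 were lower and 0 higher, also when adjusted over the list alone, including Ms4a1 (8.31-fold; camera adjusted p = 0.0982), and of 8 T and NK cell genes, 1 was lower, Klrd1 (13.3-fold), and 1 higher (3 and 1 adjusted over the list alone; camera adjusted p = 0.482). Treml4 was 22.3-fold lower and Itgax had a log2 difference of −0.06 ± 0.19 (limma adjusted p = 0.894), which turned to 0.02 with deposit set as a block and to 0.04 without WT GM-CSF + IL-4 replicate 2. The lone CD24+ DC array is assumed to vary as the replicated groups do, and limma with deposit set as a block called 1214 genes higher and 952 lower. Arrays of the earlier deposit set also made the calls, so that a direction kept within that set is no separate check. limma called 939 genes without WT GM-CSF + IL-4 replicate 2 (the earlier set alone, where all 1594 calls kept their direction), 983 without WT GM-CSF + IL-4 replicate 1 and 787 without either IRF4KO replicate. Of 46 genes named for this comparison, 3 lost their call without either WT GM-CSF + IL-4 replicate (H2-Ob at an adjusted p of 0.116 and 0.0857), 8 without either IRF4KO replicate and 1 without either WT GM-CSF replicate.

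Ly6Clo TremL4+ monocytes were compared with Ly6Chi TremL4− monocytes, 1 array against 1, and single genes were not tested, so that the values are differences only. Fabp4 was 80.4-fold higher in Ly6Clo monocytes (log2 difference 6.33), the fatty acid receptor gene Cd36 60.3-fold, Lilra5 42.8-fold, the sort marker gene Treml4 42.1-fold, the angiotensin-converting enzyme gene Ace 38.0-fold, the IgG receptor gene Fcgr4 32.3-fold, Pparg 27.2-fold and the enolase gene Eno3 20.5-fold. F13a1 was 120-fold lower (−6.90), Mmp8 95.0-fold, Fn1 65.3-fold, Kif11 58.6-fold, Ctsg 51.3-fold, the actin-capping gene Capg 39.9-fold, the lectin gene Clec5a 39.6-fold and the mitotic genes Ccnb2, Ccna2 and Bub1 38.4-fold, 34.6-fold and 32.9-fold. Of 28 nonclassical monocyte genes, 25 were higher by 2-fold or more and 0 lower, with a median of 2.80 at percentile 100 among 10000 random lists matched on expression. Of 33 cell cycle genes, 31 were lower by 2-fold or more and 0 higher, with a median of −3.57 at percentile 0.0. Of 21 classical monocyte genes, 12 were lower and 1 higher (median −1.89, percentile 0.0), and of 22 genes of lipid uptake and PPARγ or LXR targets, 9 were higher and 3 lower (median 0.47, percentile 100). Of 26 interferon-stimulated genes, 9 were lower and 0 higher (median −0.81, percentile 0.0). Of 12 early myeloid progenitor genes, which include the granule genes Elane (20.7-fold), Prtn3 (18.8-fold) and Mpo (17.4-fold), 6 were lower and 0 higher (median −1.41, percentile 0.0), and the median was −0.93 with no filter and −0.81 with the stricter filter. Of 39 transcription factor genes, 5 were higher and 5 lower by 2-fold or more (median 0.29, percentile 100). Other lists with small medians also lay at percentile 100, such as MHC class II genes (0.28, with 2 higher and 3 lower) and costimulation and maturation genes (0.25). Percentile 100 therefore does not set a list with a small median apart. Nr4a1, which Ly6Clo monocytes need and which is also an immediate early gene, was 14.3-fold higher. Of 21 immediate early and heat shock genes, 7 were higher and 0 lower by 2-fold or more (median 0.28, percentile 100). The log2 difference was 2.10 for Bcl6, −1.27 for Irf8, −2.58 for Myc and 0.35 for Irf4. Of the sort marker genes, Csf1r differed by 1.22, Itgax by 3.02 and Cd24a by −3.78. In all, 384 genes were higher and 1018 lower by 2-fold or more, 37 and 123 of them by 8-fold or more.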

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

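Both results here come from probe sets outside the comparisons above, with the test that was planned for single genes. Among 861 tested probe sets with several gene names, 21 were higher and 35 lower in IRF4KO than in WT Mo-DCs by limma. They are listed because the report's comparisons leave such probe sets out, and not for the size of these counts. Among 3649 tested probe sets with no gene name, 111 were higher and 96 lower. Both kinds had a smaller share called than the 12018 genes, of which 21.1% were called in this comparison. Which transcripts these probe sets read was not examined, and no explanation was tested.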

How the results depend on the processing

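The alternatives named here were all planned. Of 3224 results for named genes under alternatives, 2844 kept their direction and their side of the threshold, 352 kept the direction but lost the call, 20 gained a call and 8 turned in sign. Many of these genes were named for large changes, genes that stayed uncalled count as kept, and some alternatives give the same fit. The total therefore does not measure the stability of all calls. With the 4 arrays of a comparison alone, 79.3% of all IRF4KO calls and 0.0% of all IL-4 calls were kept. Camera lists at the preset correlation kept their side in 995 of 1036 results, while 27 lost a call and 14 gained one. Lists that gained a call included 2 for IRF4KO with no filter and 1 against CD24+ DCs with deposit set as a block. With an estimated correlation 54 of 80 lost their call and 0 held one. The 8 sign changes were all in genes without a call. Itgax in IRF4KO cells ranged from −0.08 to 0.15 and Csf1r from −0.49 to 0.52 when 1 replicate was left out. Against monocytes, Csf1r in GM-CSF Mo-DCs ranged from −0.55 to 0.27 and was 0.32 with deposit set as a block, and against CD24+ DCs Itgax ranged from −0.17 to 0.04 and was 0.02 with the block. The cause was not tested. Leaving out 1 replicate gave 265 to 1107 genes higher and 215 to 1017 lower in IRF4KO cells, and 0 to 74 higher and 0 to 103 lower with IL-4. Against Ly6Chi monocytes it gave 421 to 722 higher and 765 to 1102 lower in GM-CSF + IL-4, and 223 to 400 and 291 to 551 in GM-CSF. Against CD24+ DCs it gave 380 to 693 and 407 to 618. The genes higher with IL-4 and lower in IRF4KO cells then numbered 0 to 71, and those lower and then higher 0 to 67. These fits have fewer arrays and fewer residual degrees of freedom. Other shifts over 1.5 times concern IL-4, its overlap with IRF4KO and, with deposit set as a block, the genes higher in GM-CSF Mo-DCs than in monocytes. With no filter, which tests more genes, limma called 36 genes higher and 88 lower with IL-4, and the overlaps were 30 and 59. With the 4 arrays alone, limma called 0 and 0 (1550 at an unadjusted p under 0.05), and the overlaps were 0 and 0. In the replicate block the counts were 202 and 393 with overlaps of 153 and 193, and IRF4KO counts were 1027 and 949. Of 36 genes named for IL-4, 6 gained a call in that block and 1 lost it. The labels do not pair replicates. Replicate 1 minus replicate 2 correlated across genes at 0.51 between both WT cultures, as deposit set would also give, and at −0.02 and −0.08 between IRF4KO and those. With deposit set as a block the IL-4 counts were 345 and 587 with overlaps of 302 and 367, and 893 genes were higher in GM-CSF Mo-DCs than in monocytes. Why the blocks raised these counts was not tested. With different WT arrays for both effects, r across genes was −0.30 in 1 of the 2 splits. The stricter filter, another quantile normalization, the mean of a gene's probes and eBayes with trend and robust settings moved no count of called genes by over 1.5 times. No background signal was used here, so detection of weak genes was not assessed.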

Other observations

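Of the tests in this part, those of shared arrays and of deposit set for the first pattern, and the last test of splenic DCs for the third, were chosen only after the result was seen. Single genes of further groups changed in IRF4KO against WT Mo-DCs, while of these lists camera called glycolysis and hypoxia alone, a call lost with an estimated correlation. Of 25 inflammatory cytokine and chemokine genes, 4 rose and 1 fell, also when adjusted over the list alone (camera adjusted p = 0.692), including Il1a (15.7-fold) and Ccl7 (14.1-fold), which encode an alarmin and a monocyte attractant, and Ccl5, which fell. Among 14 chemokine receptor genes, 3 rose and 3 fell, also when adjusted over the list alone (camera adjusted p = 0.8), and the receptor gene Ccr1 rose 8.10-fold while Ccr7 and Cxcr2 fell. Of 7 osteoclast markers, 3 rose and 1 fell (4 and 2 adjusted over the list alone; camera adjusted p = 0.569): the protease gene Ctsk rose 6.65-fold and Dcstamp, which serves cell fusion, fell 10.8-fold. Of 22 glycolysis and hypoxia genes, 8 rose and 2 fell (10 and 2 adjusted over the list alone), with the mitophagy gene Bnip3 4.35-fold and the hexokinase gene Hk3 4.23-fold higher and the phosphofructokinase gene Pfkp 3.59-fold lower. The glycolysis list had a camera adjusted p = 0.0153 and adjusted p = 0.758 with an estimated correlation, and the camera value was 0.0564 without WT GM-CSF + IL-4 replicate 2 and 0.075 without IRF4KO replicate 2. Of 17 cholesterol synthesis genes, 1 rose and 3 fell (1 and 5 adjusted over the list alone; camera adjusted p = 0.0678), with Idi1 10.6-fold and Cyp51 2.16-fold lower, and the camera value was 0.0274 without WT GM-CSF + IL-4 replicate 2. Among 26 interferon-stimulated genes, 3 rose and 4 fell (5 and 4 adjusted over the list alone; camera adjusted p = 0.869), including the antiviral gene Mx1 (9.86-fold lower) and Stat2 (3.25-fold lower).

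In GM-CSF Mo-DCs, which received no IL-4, 13 of 35 IL-4 and STAT6 target genes were higher and 4 lower than in Ly6Chi monocytes (20 and 7 adjusted over the list alone), with Retnla 64.0-fold and Mgl2 63.8-fold higher (camera adjusted p = 7.8e-08, and adjusted p = 0.403 with an estimated correlation). Of 27 C-type lectin and scavenger receptor genes there, 8 rose and 2 fell (11 and 3 adjusted over the list alone), including the fatty acid receptor gene Cd36 (62.9-fold; camera adjusted p = 3.0e-04, and adjusted p = 0.403 with an estimated correlation). Of 26 interferon-stimulated genes, 7 were lower and 2 higher in GM-CSF + IL-4 Mo-DCs than in CD24+ DCs (9 and 2 adjusted over the list alone), including the chemokine gene Cxcl10 (12.0-fold) and Irf7 (10.1-fold; camera adjusted p = 0.0262, and adjusted p = 0.58 with an estimated correlation), and the camera value was 0.11 without WT GM-CSF + IL-4 replicate 1 and 0.137 with the stricter filter. Between deposit sets (set B minus set A), neutrophil markers had median log2 differences of −1.59 in GM-CSF + IL-4 and −0.92 in GM-CSF, inflammatory genes −1.04 and −0.43, and classical monocyte genes −0.85 and −0.71. The nuclear receptor gene Nr4a3 read 7.43 and 10.01 on the 2 GM-CSF arrays.

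The first pattern is that genes changed by IL-4 changed the opposite way in IRF4KO cells. With different WT arrays in each comparison, r across genes was −0.30 or further from 0, which argues against shared arrays as the whole source, and it was −0.53 with the IL-4 effect inside set A and the IRF4KO effect inside set B, which argues against deposit set. Of the 2541 called genes, 48.4% (1230) were also called the same way against WT cells without IL-4. This goes against a lost IL-4 response as the whole IRF4KO effect. That percentage alone does not settle it, because both comparisons use the same IRF4KO arrays and the percentage that this sharing alone gives was not simulated. The MHC class II list was lower in IRF4KO cells (median −1.15, and −1.29 within set B). It was also lower with IL-4 (−0.51, and −0.65 within set B). A lost IL-4 response alone would not lower these genes, so that this list argues against it as the whole effect. Against WT cells without IL-4, the 86 genes higher with IL-4 had a median log2 difference of −0.23 in IRF4KO cells (interquartile range −0.58 to 0.19). The 181 lower genes had one of −0.65 (−1.66 to 0.18). The arrays of WT cells without IL-4 also served to pick these genes. A part of the IL-4 response that needs IRF4 stays open as a hypothesis, because no IRF4KO cells without IL-4 were measured.

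The second pattern is the lower DC genes and higher macrophage and lysosome genes in IRF4KO cells. Monocytes left in the sort would bring their abundant transcripts, yet 122 genes at least 8-fold higher on the Ly6Chi monocyte array than in WT Mo-DCs rose by a median of 0.74 log2 units (interquartile range 0.08 to 1.92), and 20 of the 33 risen macrophage and lysosome genes lay at least 1 log2 unit above the monocyte array itself. The sort for Ly-6Clo CD11c+ cells would also remove Ly6Chi monocytes, and 55 of the 122 genes were called higher and 1 lower, so that a small share is not excluded. Deposit set is argued against by the values inside set B, where the costimulation list had a median of −1.97. IRF4 genotype remains as a hypothesis, untested beyond these 4 arrays.

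The third pattern is the rise of Clec9a in IRF4KO cells, where other cDC1 genes went both ways and Batf3 and Wdfy4 were among those that fell. Batf3 does not set these cell types apart here, with 9.78 in WT GM-CSF + IL-4 Mo-DCs and 9.59 on the CD24+ DC array. CD24+ DCs of the splenic kind among the sorted cells would need a share of 4.7% to give the Clec9a level, and of 39 genes at least 16-fold higher on the CD24+ DC array, 43.6% (17) came within 1 log2 unit of the level that this share needs. That test left it undecided, because the median rise needed was just 1.04, with 0.06 measured, and 9 of the 39 genes were called higher and 2 lower. Of the 6 genes that would rise by 2 or more log2 units, 16.7% (1) came within 1 log2 unit of the level, with a median rise of 0.04 against 2.75 needed, and Xcr1 read 4.71 where 7.20 was needed. A share too small for the Clec9a level is not excluded. The difference of Clec9a inside set B was 3.41, which argues against deposit set. A cDC1-like cell of another profile, or Clec9a expressed by the Mo-DCs themselves, may account for it, and neither was tested.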
